A study of Solanum lycopersicum and Solanum pimpinellifolium with 46 samples.

How the data were processed

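Lateral root RNA of 46 tomato plants was hybridised to a single-colour oligonucleotide array for tomato, 1 plant per array. The plants grew in garden soil under natural light at 22 to 30 °C and were sampled at the flower-bud stage, and 100 ng of RNA was labelled per sample. Per the labels, individual plants were the biological replicates, in 12 groups of 3 or 4 (2 species, 3 populations per species, control or 3 drying cycles).

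The values came as one table of intensity values as deposited, in linear units with a floor of 1; the labels do not state how probes were summarised or normalised by the authors. The table held 10209 probe sets, 196 of them at the floor in at least 1 sample. Array medians lay between 263 and 350 with a median of 315. The 108 array control probe sets were left out of the tests and 10101 remained. Values were log2-transformed with no further scaling or filter. The number of arrays limits the precision.

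The platform's annotation gave a symbol to 909 probe sets, for 802 genes, of which 176 had a placeholder name; 885 of the 909 matched the reference gene table and 24 kept the array's symbol. The remaining 9192 probe sets had no symbol and entered counts only. For the 83 genes with more than 1 probe set, that with the highest mean stood for the gene.

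Tests used limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 46 samples, with empirical Bayes moderation in the default setting, and p was adjusted by Benjamini-Hochberg over the probe sets tested; "called", "rose" and "fell" mean an adjusted p under 0.05. Contrasts were the drought response in each population, averaged within each species and over the 6 populations, the difference between the species in that response, and F tests for differences among the 3 populations of a species. Differences between the species within a treatment were tested on the 6 population means, 3 against 3, since plants of one population are not independent samples of a species. SE are those of the moderated fit. For drought responses and their differences they rest on the spread of plants within groups, not on that among populations. For species differences within a treatment they rest on the population means. All p are two-sided. Named genes were chosen by a rule: for the averaged response the 10 called genes with the largest rise and the 10 with the largest fall that moved the same way in all 6 populations; for each species the 5 largest each way that moved the same way in its 3 populations; for the interaction and F tests the 10 of smallest p; for the species differences up to 8 each way whose populations did not overlap; and for each list up to 4 members of smallest p. The genes whose range over populations is given were chosen after their values were seen.

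The gene lists, the alternatives and the tests were chosen before the data were examined, except where stated. Of 24 fixed lists, 17 had the 5 measured genes needed for a test: abscisic acid, heat shock, reactive oxygen scavenging, peroxidases and lignin, cell wall, ethylene, jasmonate and wounding, pathogenesis-related, auxin with gibberellin and cytokinin, mineral transport, sucrose with hexose and starch, ribosomal, histones and cell cycle, stress transcription factors, lipid, green shoot, and seed and flower. A further 8 lists of symbols on the array were put together after the table was seen and before any comparison was computed: water deficit, ascorbate and glutathione, isoprenoids and carotenoids, MAP and calcium-dependent kinases, amino acids with GABA and polyamines, 14-3-3 proteins, subtilisin-like proteases, and flower and fruit identity genes. The annotation gave symbols only, so lists were matched on symbols and caught a few unrelated genes. Lists were tested with camera in limma with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Camera set the members against all 10101 probe sets, while members came from the 802 named genes alone. In the averaged response 209 named genes rose and 290 fell, where 3057 of all probe sets rose and 2537 fell. In the interaction 155 were more positive in S. pimpinellifolium and 96 in S. lycopersicum, against 1389 and 1209 of all. A call in the direction of this lean may in part reflect named genes as a whole. Camera was not run against named genes alone.

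The procedure was tested on simulated data with known changes at log2 sizes of 0.5, 1 and 2. The averaged response recovered 70.1, 94.0 and 98.5% of them, with 2.78% of calls false, and the interaction 31.3, 67.2 and 93.9%, with 9.22% false. For both, simulated populations of a species shared the same drought response. These false shares therefore do not cover differences in response among populations. The species difference in control plants recovered 0, 10.4 and 74.2%, and the response of 1 population 19.4, 53.7 and 89.4%. Camera called the raised list and 0 of 20 unchanged lists. Simulated probe sets varied independently of each other, so this result does not cover lists whose members vary together. In the averaged response the estimated correlation of the real lists ran from 0.031 for water deficit to 0.292 for green shoot. With estimated correlations 0 lists were called in that response.

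Alternatives were centred array medians, quantile normalization, leaving out the dimmest 25% of probe sets, array weights, moderation with trend and robust, a fold limit of 2, 16 added to each value, the replicate number as a block, each library, replicate number and population left out in turn, population-level and individual-level replicates, a random population block, fits on own samples, and the mean of a gene's probe sets. Leaving out the 3 libraries with an array weight under 0.25, together or by treatment, was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.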

Results

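Gene expression in lateral roots was measured on 46 single-colour arrays in plants of Solanum lycopersicum, the cultivated tomato species, and Solanum pimpinellifolium, the wild currant tomato. Each species was represented by 3 natural populations, numbered 2618, 1421 and 2789 in the former (hereafter lycopersicum) and 1597, 1630 and 1592 in the latter (hereafter pimpinellifolium). Plants at the flower-bud stage were either watered throughout or taken through 3 cycles of drying until the leaves wilted. The 12 groups held 4 plants each, except the 1597 and 1592 control groups with 3 each, which gave 24 arrays for lycopersicum and 22 for pimpinellifolium. The values were linear intensities of 10101 probe sets, and the median intensity per array lay between 263 and 350. Only 909 probe sets carried a gene symbol, for 802 genes, so that named genes and gene lists describe a small part of each response. The question addressed was how root transcript levels changed with water shortage and how the species and their populations differed in that change.

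Correlations across probe sets ran from 0.880 to 0.988 within a group (median 0.975) and from 0.821 to 0.991 between groups (median 0.927). The highest correlation of any pair, 0.991, joined 1597 drought replicate 3 and 1597 control replicate 1. The library 1592 drought replicate 4 correlated most with a control of lycopersicum population 1421 (0.985), against a median of 0.9145 with its own group. A drought score was computed for each library from the response of the 5 other populations, with 0 at the midpoint between the control and drought means of its own population. It was above 0 in every library labelled drought except 1597 drought replicate 3, at -0.49, and 1592 drought replicate 4, at -0.46. All control libraries scored at -0.16 or lower. These libraries and 1597 control replicate 2 had array weights (limma) of 0.196, 0.181 and 0.109 and were the only ones under 0.25. In 1597 control replicate 2 the actin control probe sets differed by 5.59 on the log2 scale between the 3' and 5' ends, a sign of RNA quality whose median over the arrays was 1.34. The comparisons kept every library as labelled, and the number of called probe sets of each comparison is also given without these 3 libraries.

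**Figure D1:**
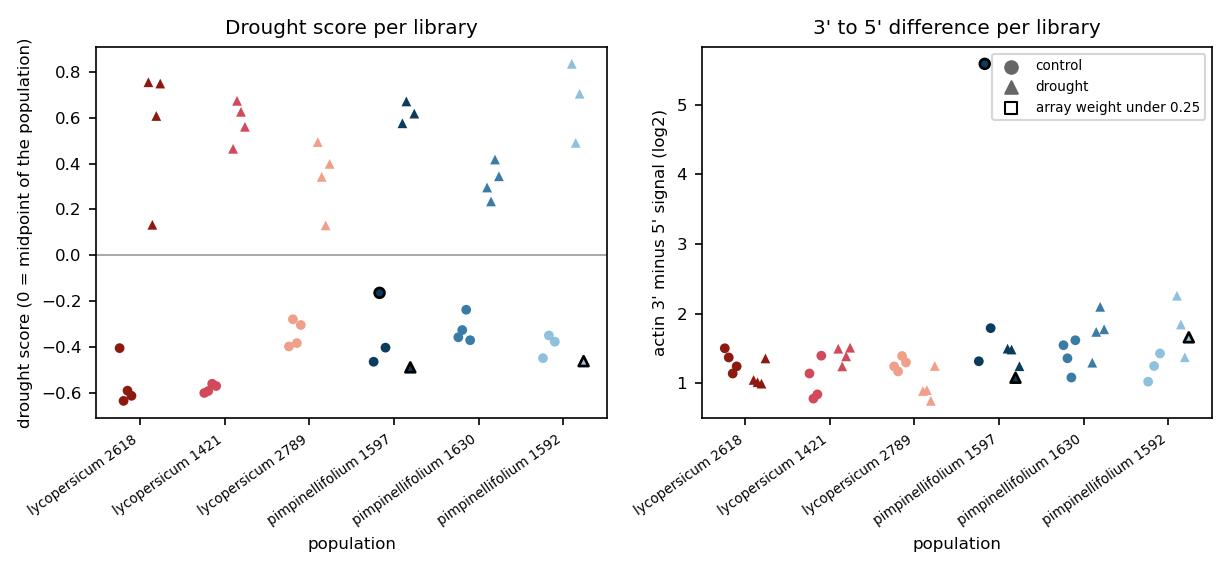
Drought score (left; 0 is the midpoint of the library's own population, no unit) and 3' minus 5' signal of the actin control probe sets (right; log2) for each of the 46 libraries, by population. Circles are controls, triangles drought plants, and a black outline marks the 3 libraries with an array weight under 0.25; the outlined triangles sit among the controls at -0.49 and -0.46, and the outlined circle stands at 5.59 in the right panel.

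In the response averaged over the 6 populations, TAS14, a dehydrin that accumulates in drying and salt-stressed tissue, rose by 2.91 ± 0.27 on the log2 scale (SE, 24 drought against 22 control plants), a 7.52-fold rise from an intensity of 1200 to 9060. SNF4, a regulatory subunit of SNF1-related kinases, rose 18.6-fold (4.21 ± 0.41), and the DREB1 transcription factor, of the family that binds dehydration-responsive elements, rose by 2.32 ± 0.29. CEVI-1, a peroxidase, fell by 4.46 ± 0.44, and opr2, a 12-oxophytodienoate reductase, fell by 3.99 ± 0.37. The cell-wall enzyme gene XET2, a xyloglucan endotransglycosylase, fell by 3.72 ± 0.36. Among the other large rises were the chitinases CHI17 (3.25) and CHI3 (2.25), the small heat shock proteins ER-SHSP (2.96) and HSP21 (2.74), and the lipid transfer protein TSW12 (2.43). PSY2, a phytoene synthase of the carotenoid pathway, rose by 2.00 ± 0.15, and NCED1, whose product carries out the key step of abscisic acid synthesis, by 1.80 ± 0.17. Falls were also measured for the phosphate transporter PT2 (-3.16 ± 0.34), the sulfate transporter ST3 (-3.04 ± 0.30) and the cell-wall invertase LIN8 (-3.23 ± 0.34). ARPI (-3.87), BR1 (-3.64), the peroxidase TPX2 (-3.59) and Dif54 (-3.29) fell as well. Genes were named here only if they moved the same way in all 6 populations, 10 in each direction by size, and their adjusted p ran from 2.74e-12 for PSY2 to 1.50e-07 for ER-SHSP.

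In all, limma called 5594 of the 10101 probe sets (Benjamini-Hochberg, adjusted p under 0.05), of which 3057 rose and 2537 fell; 948 changed at least 2-fold, 291 upwards and 657 downwards. Of the 802 named genes, 209 rose and 290 fell. Without the 3 libraries of low weight, 6119 probe sets were called. With the 6 populations as the replicates the count was 1987 (2589 without the 3 libraries), and NCED1 no longer passed, at an adjusted p of 0.057. Folds of dim genes depended on the scale: with 16 added to each intensity, SNF4 rose 7.70-fold and on the log2 scale CEVI-1 stood at -2.59 and XET2 at -2.37. Dif54 then stood at -2.05, LIN8 at -2.51, PT2 at -2.50, HSP21 at 2.11 and DREB1 at 1.365. All were still called.

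**Figure D2:**
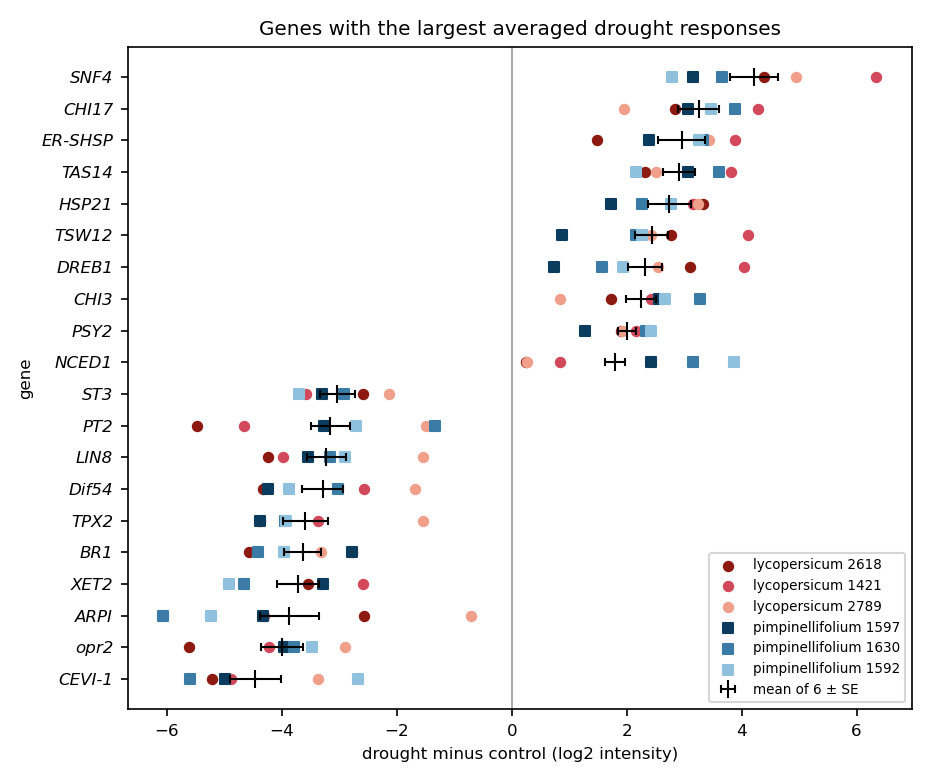
Drought minus control (log2 intensity) of the 20 genes named for the averaged response, in each of the 6 populations (circles lycopersicum, squares pimpinellifolium) and as the mean of the 6 (black). Bars are the SE of the moderated fit, from plants within groups, and do not show the spread among populations. All points of a gene lie on one side of 0, as required for naming it, and NCED1 lies between 0.25 and 0.84 in lycopersicum and between 2.42 and 3.86 in pimpinellifolium.

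Of 36 measured genes of ethylene synthesis and response 3 rose, 20 fell and 13 did not pass in the averaged response (camera, adjusted p = 0.00202; adjusted p = 0.706 with an estimated correlation). The falls lay mostly in lycopersicum, where 24 fell and 1 rose, while in pimpinellifolium 5 fell and 11 rose. ACS6, an enzyme making the ethylene precursor, fell by 1.95 ± 0.20, and ACO6, which turns it into ethylene, fell by 2.23 ± 0.27. The response factor ERF-H1 (-2.13 ± 0.24) and the signalling kinase CTR1 (-0.66 ± 0.10) fell too. Of 12 genes of reactive oxygen scavenging 1 rose and 7 fell (camera, adjusted p = 0.0449; adjusted p = 0.706 with an estimated correlation), among them the superoxide dismutase SODCP.2 (-1.09 ± 0.13), the ascorbate peroxidase APX2 (-0.58 ± 0.08) and the glutathione transferase GST-T4 (-1.08 ± 0.18). Of 7 genes of peroxidases, lignin and suberin 1 rose and 4 fell (camera, adjusted p = 0.0449; adjusted p = 0.706 with an estimated correlation): the peroxidases CEVI-1, TPX2, CEVI57 (-2.85 ± 0.37) and cevi19 (-1.83 ± 0.24). This list also held TomloxE, a lipoxygenase that its symbol pattern had picked up. Leaving out the low-weight library 1597 control replicate 2, or 1421 drought replicate 1, 2789 drought replicate 1, 1592 drought replicate 2, 1421 control replicate 4 or 2789 control replicate 4, left 1 called list in the averaged response.

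Other fixed lists were not called by camera in the averaged response. In cell wall loosening and remodelling, 12 of 38 members rose and 16 fell; the pectin methylesterase PMEU1 (-2.16 ± 0.19) and the expansin EXPA6 (-2.05 ± 0.21) were among the falls. All 5 abscisic acid genes changed, 3 upwards, including the transcription factor AREB1 (1.69 ± 0.14), and 2 downwards, the aldehyde oxidases TAO3 (-0.68) and AO1 (-0.36). Heat shock proteins and chaperones gave 3 rises and 1 fall among 6, the fall being Hsp90-1 (-1.10 ± 0.14). Among 14 jasmonate and wound genes 1 rose and 6 fell, among 11 pathogenesis-related genes 3 rose and 5 fell, and among 10 auxin, gibberellin and cytokinin genes 2 rose and 3 fell. Of 15 mineral nutrient and ion transporters 6 rose, including the proton pump LHA1 (0.61 ± 0.08) and the sodium antiporter NHX1 (0.73 ± 0.10), and 6 fell. Of 23 genes of sucrose, hexose and starch 4 rose, including the sucrose phosphate synthase SPS (0.90 ± 0.08), and 8 fell, including the hexose transporter HT1 (-1.58 ± 0.18). Histones and cell cycle genes gave 1 rise and 5 falls among 12, with the cyclin CycB2 at -1.03 ± 0.15 and the mitotic kinase CDKB2 at -0.67 ± 0.14; this list also held NSY, a carotenoid enzyme. Stress transcription factors gave 4 rises and 6 falls among 11 (DREB2 fell by 1.42 ± 0.19); GLB2, a rise of 0.66 in that list, is named like a haemoglobin. Lipid transfer proteins and lipid enzymes gave 3 rises and 3 falls among 8, including the phospholipases PLDa3 (1.36 ± 0.13) and PLDb1 (-2.45 ± 0.25). Of 5 ribosomal protein genes 0 passed limma's threshold, and their adjusted p started at 0.101.

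Markers of green shoot tissue rose in 4 of 8 genes and fell in 0, with the photosystem proteins PSBR at 0.75 ± 0.10 and PSBP at 0.92 ± 0.19 (camera, adjusted p = 0.258). The seed and flower list gave 2 rises and 2 falls among 9, and those 4 were AGP-S2, AgpL1 and AGP-1, named like subunits of the starch enzyme ADP-glucose pyrophosphorylase, and AGAL, named like an alpha-galactosidase. Some lists had too few measured members for a test. The dehydrin list held TAS14 and ER5 (-0.41 ± 0.17), the osmolyte list PRO2 of proline synthesis (0.53 ± 0.08) and ADC (0.02 ± 0.09), and the aquaporin list pip1 (1.38 ± 0.26) and Sip1 (0.25 ± 0.07). Fermentation was represented by the alcohol dehydrogenase ADH2 (-0.61 ± 0.11), ubiquitin by UBC27 (0.13 ± 0.05) and LOC543683 (0.06 ± 0.06), and the vascular list by PP2AC1 (-0.25 ± 0.05) and PP2Ac2 (-0.17 ± 0.05), which encode phosphatase subunits and not phloem proteins. The root hair list had 0 measured members. Counts adjusted over the list alone equalled these for every fixed list. For minerals the median (0.17) and the camera direction were upward and the mean (-0.54) downward; for seed and flower the median was 0.00433 and the mean and camera direction were downward. The ribosomal median, -0.02, turned to 0.00477 with quantile normalization.

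In lycopersicum the kinase subunit SNF4 rose by 5.23 ± 0.57 on the log2 scale (SE, 12 drought against 12 control plants), the heat shock protein HSP21 by 3.24 ± 0.51 and DREB1 by 3.23 ± 0.41. Control intensities of these genes were low (10.7, 21.0 and 8.22), so the size of the rises depended on the scale: with 16 added to each intensity they were 3.85, 2.47 and 1.92, all called. TSW12 rose by 3.10 ± 0.39 and CHI17 by 3.03 ± 0.50. The largest falls were CEVI-1 (-4.50 ± 0.60), opr2 (-4.25 ± 0.50), PT2 (-3.88 ± 0.47), the cold- and drought-response factor CBF1 (-3.86 ± 0.59, from an intensity of 6980 to 480) and Prg1 (-3.82 ± 0.55). CEVI-1 ended near the floor, at 3.82, and with 16 added its fall was -2.36, smaller than those of opr2 (-4.13), CBF1 (-3.75), Prg1 (-3.66) and PT2 (-2.97). In all 5185 probe sets were called by limma, 2793 higher and 2392 lower, and 1452 of them at least 2-fold; 5650 were called without the 3 low-weight libraries, none of which was labelled lycopersicum. Quantile normalization moved the median change of all probe sets from 0.03 to 0.12, giving 3517 higher and 2065 lower.

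Ethylene genes fell in lycopersicum: 24 of 36 fell, 1 rose and 11 did not pass (camera, adjusted p = 8.08e-08; adjusted p = 0.312 with an estimated correlation). The falls included ACS6 (-3.26 ± 0.28), the response factor PTI5 (-3.04 ± 0.31), the receptor ETR4 (-1.89 ± 0.22) and CTR1 (-1.18 ± 0.13). Of 14 jasmonate and wound genes 9 fell and 1 rose (camera, adjusted p = 0.0331; adjusted p = 0.576 with an estimated correlation), among them the synthesis enzymes AOC (-1.30 ± 0.22) and AOS (-1.88 ± 0.38). All 11 stress transcription factors changed, 4 upwards and 7 downwards; NAC1 stood at -2.83 ± 0.32 and DREB2 at -2.63 ± 0.27 (camera, adjusted p = 0.142). Pathogenesis-related genes gave 2 rises and 6 falls among 11, including the glucanase GluB (-2.10 ± 0.18) and PR-5 (-2.06 ± 0.29), with a camera adjusted p of 0.0839. Heat shock proteins gave 3 rises and 2 falls among 6, reactive oxygen scavenging 0 and 6 among 12, peroxidases and lignin 2 and 4 among 7, and minerals 4 and 5 among 15. Among 38 cell wall genes 17 rose and 15 fell, and among 23 sucrose, hexose and starch genes 5 rose and 9 fell, with the invertase Wiv-1 at -2.86 ± 0.36.

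Markers of green shoot tissue moved with these groups: 6 of 8 rose and 0 fell in lycopersicum, with PSBR at 1.15 ± 0.13, PSBP at 1.19 ± 0.26 and the light-harvesting gene CAB4 at 1.02 ± 0.26 (camera, adjusted p = 0.0799). The CAB4 rise was not shared by all populations: it stood at -0.99 in 2618, 1.17 in 1421 and 2.86 in 2789. Adjusted over the list alone, 16 cell wall genes and 2 instead of 3 of the histone and cell cycle genes fell. Median and mean differed in sign for minerals (0.11 and -0.56, camera down) and lipids (-0.10 and 0.07, camera down). Ribosomal genes had a median of 0.04 with a downward camera direction, and the seed and flower list a median of -0.02 with an upward one. Quantile normalization turned the medians of the lipid list to 0.00430 and of the seed and flower list to 0.07.

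In pimpinellifolium CHI17 rose by 3.47 ± 0.52 on the log2 scale (SE, 12 drought against 10 control plants), SNF4 by 3.20 ± 0.60 (2.04 with 16 added to each intensity, from a control intensity of 8.02) and NCED1 8.85-fold (3.15 ± 0.25, from an intensity of 106 to 940). ER-SHSP rose by 2.99 ± 0.59 and TAS14 by 2.94 ± 0.40. The largest falls were ARPI (-5.21 ± 0.73), CEVI-1 (-4.42 ± 0.63), XET2 (-4.29 ± 0.52), TPX2 (-4.09 ± 0.57) and opr2 (-3.74 ± 0.53). CEVI-1 and XET2 ended near the floor, at intensities of 9.22 and 12.4, and with 16 added the fall of CEVI-1 was -2.82, smaller than those of ARPI (-4.64), opr2 (-3.63) and TPX2 (-3.47). In all 4149 probe sets were called by limma, 2312 higher and 1837 lower, 993 of them at least 2-fold. Without the low-weight libraries 4962 were called and each named change was larger: CHI17 stood at 4.24, SNF4 at 3.90, NCED1 at 3.28, ER-SHSP at 3.62, TAS14 at 3.22, ARPI at -6.31, CEVI-1 at -5.06, XET2 at -5.32, TPX2 at -4.70 and opr2 at -4.57.

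The peroxidase, lignin and suberin list fell in pimpinellifolium in 5 of 7 members and rose in 0 (camera, adjusted p = 0.00246; adjusted p = 0.16 with an estimated correlation), with cevi19 at -2.09 ± 0.35 and the lignin enzyme CCR1 at -0.56 ± 0.14. Cell wall genes gave 4 rises, 15 falls and 19 without a call among 38 (camera, adjusted p = 0.00246; adjusted p = 0.369 with an estimated correlation). The expansin EXPA8 (-3.33 ± 0.46), PMEU1 (-2.16 ± 0.27) and the xyloglucan enzyme XTH16 (-2.02 ± 0.28) fell. Reactive oxygen scavenging gave 1 rise, the glutathione peroxidase GPXle-1 (0.43 ± 0.08), and 7 falls among 12 (camera, adjusted p = 0.0193; adjusted p = 0.419 with an estimated correlation). Of 36 ethylene genes 11 rose and 5 fell (camera, adjusted p = 0.946); ACS3 rose by 2.17 ± 0.44 and ACO6 fell by 2.89 ± 0.39. Abscisic acid genes gave 3 rises and 0 falls among 5, with TAO2 at 0.40 ± 0.11, and stress transcription factors 5 rises and 0 falls among 11, with DREB3 at 1.02 ± 0.30. The aquaporin pip1 rose by 2.13 ± 0.38. Of 8 green shoot markers 1 rose and 1 fell.

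Adjusted over the list alone in pimpinellifolium, the falls were 6 for peroxidases and lignin, 17 for the cell wall, 6 for minerals (4 over all probe sets), 7 for sucrose (6) and 3 for jasmonate (4). Lipid genes gave 4 rises (3), the seed and flower list 0 (1), and green shoot markers 0 rises and 0 falls (limma; 1 and 1 over all probe sets). Median and mean differed in sign for jasmonate (0.19 and -0.32, camera down), minerals (0.09 and -0.51, camera up) and sucrose, hexose and starch (0.06 and -0.22, camera down).

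**Figure D3:**
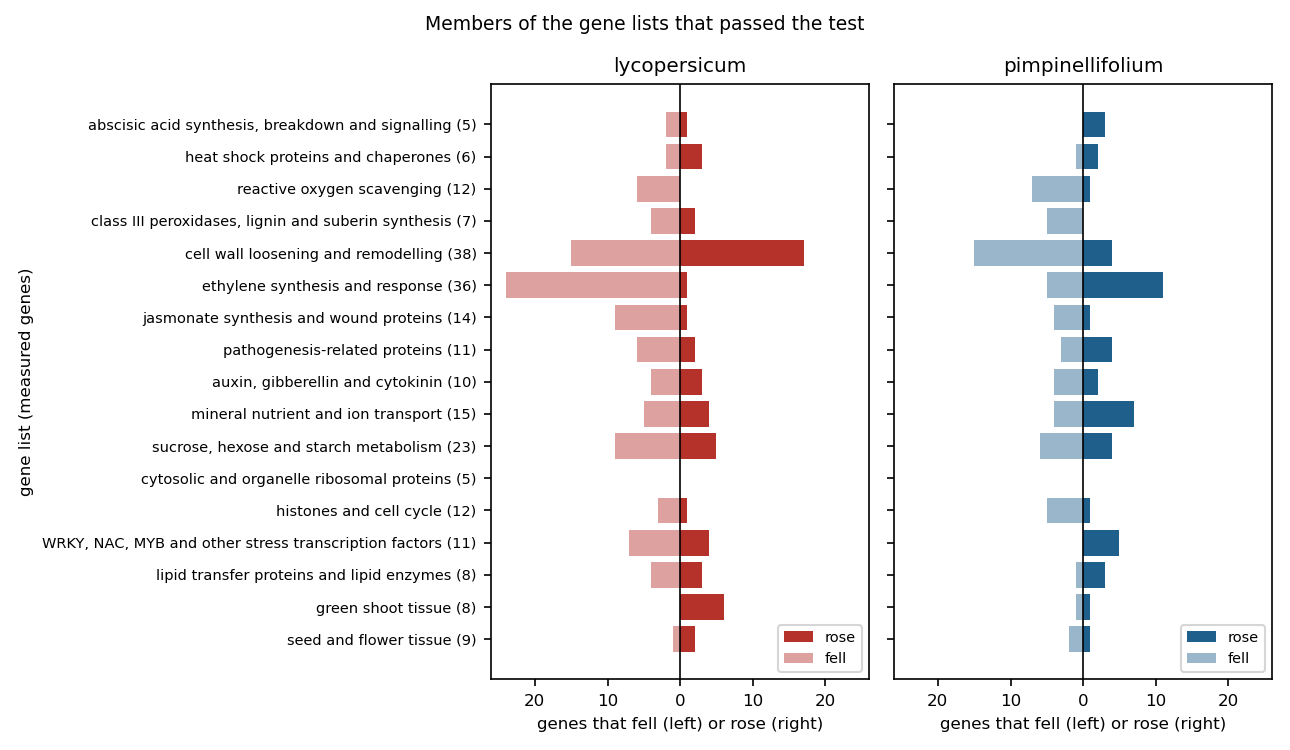
Number of members of each fixed gene list that rose (right of 0) or fell (left of 0) with drought in lycopersicum (red) and pimpinellifolium (blue), adjusted over all probe sets, with the number of measured genes in brackets. Ethylene genes show 1 rise and 24 falls in lycopersicum against 11 and 5 in pimpinellifolium.

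The drought response was compared between the species as the response in pimpinellifolium minus that in lycopersicum. PTI5, an ethylene response factor of defence, fell by 3.04 ± 0.31 in lycopersicum and rose by 1.09 ± 0.33 in pimpinellifolium, a difference of 4.13 ± 0.45 (adjusted p = 1.31e-07). The ethylene synthesis genes ACS1A and ACS3 differed by 2.82 ± 0.36 and 4.34 ± 0.60; ACS3 fell by 2.17 in one species and rose by 2.17 in the other. DES, a divinyl ether synthase of oxylipin metabolism, fell by 3.21 ± 0.25 in lycopersicum and stood at 0.07 ± 0.27 in pimpinellifolium. NCED1 stood at 0.45 ± 0.24 in lycopersicum and rose by 3.15 ± 0.25 in pimpinellifolium; under drought its intensities were 1020 and 940, and in control plants 745 and 106. The amino acid permease AAP2 (difference 1.47 ± 0.16), the hexose transporter HT2 (2.09 ± 0.29), LEA14 of the late embryogenesis abundant proteins (0.88 ± 0.12) and the kinase MPK3 (3.39 ± 0.48) fell in lycopersicum and rose in pimpinellifolium. The receptor ETR4 differed by 2.34 ± 0.32. Both other probe sets of MPK3 were called in the same direction.

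**Figure D4:**
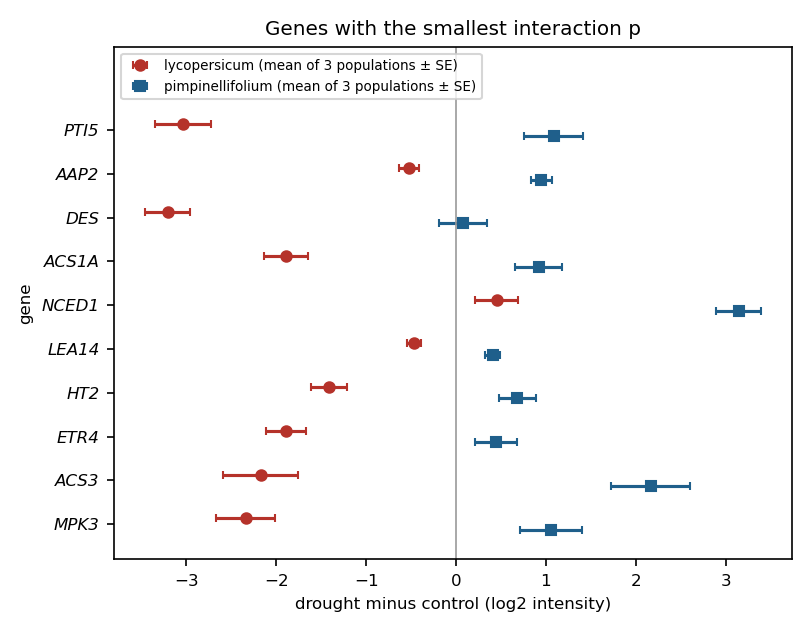
Drought minus control (log2 intensity) in lycopersicum (red circles) and pimpinellifolium (blue squares), for the 10 genes with the smallest p for the difference. Each point is the mean of 3 populations. Bars are the SE of the moderated fit, from plants within groups, and do not show the spread among populations. PTI5 lies at -3.04 and 1.09, NCED1 at 0.45 and 3.15.

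In all 2598 probe sets differed in response (limma), 1389 with the more positive response in pimpinellifolium and 1209 in lycopersicum; 3288 differed without the 3 low-weight libraries, split 1517 to 1771. Quantile normalization gave 1205 to 1752 and centred array medians 1276 to 1414, so that the balance of directions depended on scaling and on these libraries. Of the 2598, 1256 were called in lycopersicum alone, 638 in pimpinellifolium alone, 353 in both with opposite directions, 220 in both with the larger change in lycopersicum and 64 in both with the larger change in pimpinellifolium. Without the 3 libraries the last 2 classes were 249 and 412. With the 3 populations of each species as replicates limma called 0 probe sets (1697 at an unadjusted p under 0.05; 0 and 1929 without the 3 libraries), and the 10 genes above had adjusted p from 0.0967 to 0.254, so that the difference holds for these populations and was not shown for the species at large.

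In the ethylene list, which had the smallest p by camera for the difference between the species, 22 of 36 members had the more positive response in pimpinellifolium, 1 in lycopersicum, and 13 did not pass (camera, adjusted p = 9.38e-09; adjusted p = 0.109 with an estimated correlation). Stress transcription factors gave 7 and 1 of 11 (camera, adjusted p = 0.00246; adjusted p = 0.109 with an estimated correlation), including NAC1 (3.06 ± 0.47), DREB3 (2.67 ± 0.41) and DREB2 (2.42 ± 0.39). Pathogenesis-related genes gave 4 and 0 of 11 (camera, adjusted p = 0.00447; adjusted p = 0.29 with an estimated correlation), including GluB (1.48 ± 0.26) and the chitinase CHI9 (0.86 ± 0.19). Jasmonate and wound genes gave 5 and 0 of 14 (camera, adjusted p = 0.035; adjusted p = 0.382 with an estimated correlation), including the lipoxygenase loxD (2.08 ± 0.33), AOS (2.82 ± 0.56) and AOC (1.61 ± 0.31). Cell wall genes went the other way, with 3 more positive in pimpinellifolium and 13 in lycopersicum of 38 (camera, adjusted p = 0.0173; adjusted p = 0.382 with an estimated correlation), including the expansins exp9 (-1.92 ± 0.37) and exp18 (-1.67 ± 0.36). Markers of green shoot tissue differed in the same direction as the cell wall genes, PSBR by -0.80 ± 0.19 and CAB4 by -1.44 ± 0.38, which were the 2 of 8 that passed (camera, adjusted p = 0.0295; adjusted p = 0.382 with an estimated correlation). Within lycopersicum CAB4 moved in opposite directions, from -0.99 in population 2618 to 2.86 in population 2789. Without the 3 low-weight libraries the jasmonate and green shoot calls ended, each at an adjusted p of 0.0668. With all libraries, 155 of the 802 named genes had the more positive response in pimpinellifolium and 96 in lycopersicum. The lists were not tested against the named genes alone.

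Single genes of other lists also differed between the species: IAA3, an auxin response repressor, by 4.79 ± 0.77, the potassium channel LKT1 by 1.41 ± 0.22, the aquaporin pip1 by 1.51 ± 0.53, ER5 by 2.37 ± 0.34 and the desaturase Fad7 by 2.45 ± 0.41. The sodium antiporter NHX1 differed by -0.77 ± 0.19. Adjusted over the list alone, the members more positive in lycopersicum were 2 for ethylene, 3 for peroxidases and lignin (2 over all probe sets), 14 for the cell wall, 4 for histones and cell cycle (3) and 2 for lipids (1). Those more positive in pimpinellifolium were then 4 for the cell wall, and 1 each (0) for peroxidases and lignin and for histones and cell cycle. For auxin, gibberellin and cytokinin the median (-0.30) and the camera direction were negative and the mean (0.21) positive; for minerals the median was -0.02 with a positive mean and camera direction. Medians near 0 changed sign with scaling for heat shock proteins (0.00256; -0.04 with centred medians) and for sucrose, hexose and starch (0.06; -0.02 with quantile normalization).

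The responses of the species were also compared as a whole. Across the 10101 probe sets the log2 changes correlated with a Pearson r of 0.546 and a Spearman rho of 0.444, a description only, since genes are not independent replicates; without the 3 low-weight libraries these were 0.604 and 0.491. Of the probe sets called, 1305 rose in both species where 639.3 would be shared by independent lists, 1017 fell in both (435.0), and 353 went in opposite directions (1055). The SD of the log2 changes was 0.841 in lycopersicum and 0.707 in pimpinellifolium, or 0.847 in pimpinellifolium without the 3 libraries. Responses of 2 populations correlated with a median r of 0.655 within lycopersicum, 0.438 within pimpinellifolium (0.693 without the 3 libraries) and 0.408 between the species (0.435 without them).

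The drought response was also compared among the populations of lycopersicum (4 plants per group). RNALE, a ribonuclease of phosphate-starved tomato tissue, changed by 1.08 in 2618, 1.77 in 1421 and -1.54 in 2789 (limma F test, adjusted p = 0.000199). The receptors ETR4 and ETR5 stood at -3.83 and -2.16 in 2789, against -1.01 and -0.23 in 2618 and -0.85 and -0.25 in 1421. CAB4, a chlorophyll-binding protein, stood at -0.99, 1.17 and 2.86 in 2618, 1421 and 2789, and CIP1 at -1.02, 0.98 and 3.27. AGP-S2 (0.54, 0.27 and 1.17), CPA (-0.14, -0.72 and 0.27), WRKY2 (0.58, -0.11 and 1.07), LEA14 (-0.98, -0.45 and 0.04) and abz1 (1.09, 2.50 and -0.57) completed the 10 genes of smallest p, with adjusted p up to 0.00643. Without replicate number 2 of every group RNALE, ETR4 and AGP-S2 alone still passed, and without number 3 RNALE, ETR5 and CAB4. In all 391 probe sets differed, 47 of the 802 named genes among them, and 1353 without the 3 low-weight libraries. No library labelled pimpinellifolium enters the lycopersicum changes, so leaving such libraries out altered only the spread shared by all groups. The count was 622 without 1597 control replicate 2, 640 and 247 without 1421 drought replicates 1 and 2, 249 and 598 without 1421 control replicates 3 and 4, 198 and 234 without 2789 drought replicates 2 and 3, and 258 and 238 without 2789 control replicates 1 and 3.

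Among the populations of pimpinellifolium the smallest p was that of the iron superoxide dismutase FESOD, which stood at -0.24 in 1597, -1.47 in 1630 and 0.83 in 1592 (limma F test, adjusted p = 6.17e-05; 3 or 4 plants per group). FESOD had 1 other probe set, which did not differ (adjusted p = 0.978), and the mean of both was not called (adjusted p = 0.682), so that this difference rests on a single probe set. ZEP, the zeaxanthin epoxidase upstream of abscisic acid, stood at 0.46, 1.44 and 2.34 in the same order, THOM1 at -0.11, 1.04 and 2.27, RNALE at 0.26, 2.71 and 1.26 and DDTFR18 at -0.65, 1.55 and 0.57. The ethylene synthesis gene ACS8 stood at -1.54, 2.86 and 1.99. ER21 and the mitochondrial small heat shock protein MTSHP stood at -2.42 and -2.50 in 1630 and above 0 in the other two populations. The receptor kinases PRK1 (2.40 in 1592) and PRK2 (2.38 in 1592) were dim, with a mean intensity of 8.26 for PRK1 in controls, near the floor of 1. In all 727 probe sets differed and 615 without the 3 low-weight libraries. Without 1597 control replicate 2 the count was 25, and ZEP, THOM1, RNALE, PRK2, ACS8, DDTFR18 and MTSHP no longer passed (adjusted p from 0.0501 to 0.0785). Without replicate number 2 of every group FESOD alone still passed. The count was 1797 and 1365 without 1597 control replicates 1 and 3, and 291, 460, 1102 and 213 without 1597 drought replicates 1, 2, 3 and 4. It was 401 and 442 without 1630 drought replicates 2 and 3, 440 and 462 without 1630 control replicates 2 and 3, and 414 without 1592 control replicate 1.

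Tested in each population, limma called 3232 probe sets in 2618, 3030 in 1421, 2934 in 2789, 2375 in 1597, 2104 in 1630 and 2404 in 1592 (4 drought plants against 3 or 4 control plants). Without the 3 low-weight libraries these were 3898, 3719, 3645, 2561, 2867 and 3576. PT2 varied between populations from -1.34 in 1630 to -5.48 in 2618. In 1597 the count was 640 without control replicate 2 and 1443, 1509 and 1156 without drought replicates 1, 2 and 4; in 1592 it was 1439 and 1546 without control replicates 1 and 3. Fitted on their own libraries alone, 1597 gave 0 probe sets (limma; 1754 at an unadjusted p under 0.05) and 1592 gave 374. In each of these populations 2 of 35 splits of the samples gave as many called probe sets as the labels did, the labelled split included. The other split, with 3323 called in 1597 and 2959 in 1592, set a low-weight drought library among the controls. These libraries were 1597 drought replicate 3 and 1592 drought replicate 4. Chance was not excluded by this count, which the place of those libraries decided.

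In control plants, with the 6 population means as the values (3 against 3), the polygalacturonase TAPG1, known from abscission zones, was higher in pimpinellifolium by 2.51 ± 0.30 on the log2 scale (adjusted p = 0.021), at intensities of 19.4 and 3.42 near the floor. With 16 added to each intensity the TAPG1 difference was 0.90 and no longer passed (adjusted p = 0.0677). The terpene synthase MTS1 was lower in pimpinellifolium by -3.38 ± 0.40, where it was dim (an intensity of 9.17 against 95.4), and by -2.12 with 16 added, still called. Also lower in pimpinellifolium were the GABA transaminase GABA-TP3 (-2.31 ± 0.27), the ethylene synthesis gene ACS1A (-1.69 ± 0.19), the glucosyltransferase twi1 (-1.63 ± 0.21), ribA (-1.55 ± 0.22) and MYC2, a regulator of jasmonate responses (-1.20 ± 0.14). In all 111 probe sets differed by limma, 19 higher and 92 lower in pimpinellifolium, and 84 without the 3 low-weight libraries; centred array medians gave 29 higher and 75 lower, and quantile normalization 27 and 70. Without 1597 control replicate 3 the count was 60, and GABA-TP3, ACS1A, twi1 and ribA no longer passed (adjusted p from 0.0529 to 0.124); ribA was also lost with centred array medians (0.0563) and quantile normalization (0.0587). With any population of lycopersicum left out none of these genes passed. The count also fell to 28 without 1630 and 39 without 1592, and was 337 without 1597. With plants instead of populations as replicates the count was 2945. Array probes made for cultivated tomato can bind the wild species' transcripts less well, a limit that these values do not separate from abundance.

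No list was called by camera in control plants, and the smallest adjusted p was 0.148, for stress transcription factors and for the cell wall. Of the fixed lists only the ethylene list held a called member, ACS1A, and ACS7 stood at -3.60 ± 0.68 and EIN2 at 1.36 ± 0.23 without passing. Adjusted over the list alone, 3 ethylene genes were higher and 8 lower in pimpinellifolium, and 3 jasmonate genes and 3 stress transcription factors were lower; abscisic acid, minerals and lipids each had 1 lower member and auxin, gibberellin and cytokinin 1 higher. For auxin, gibberellin and cytokinin the median was 0.14 and the mean -0.12 (camera up), and for green shoot markers 0.03 and -0.08 (camera up). The seed and flower median was -0.01 with an upward camera direction. The medians of reactive oxygen genes (-0.09) and of the seed and flower list changed sign under both other scalings.

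Under drought the polygalacturonase TAPG4 was higher in pimpinellifolium by 3.57 ± 0.18 on the log2 scale (population means, 3 against 3, adjusted p = 0.00823). TAPG4 was dim in lycopersicum, with an intensity of 7.22 near the floor against 85.8 in pimpinellifolium, and with 16 added the difference was 2.18, still called. TAPG1 was higher by 3.14 ± 0.44, at intensities of 31.2 and 3.55, but with 16 added to each intensity the difference was 1.42 and not called (adjusted p = 0.0575). Fad7, a desaturase making trienoic fatty acids, was higher by 2.44 ± 0.31, the auxin response repressor IAA2 by 2.14 ± 0.22, and EIN2, a central protein of ethylene signalling, by 1.33 ± 0.15. The mitochondrial uncoupling protein UCP (0.99 ± 0.16), LePK4 (0.98 ± 0.13) and the glutamate dehydrogenase gdh1 (0.77 ± 0.12) were also higher. SNF4 was lower by -2.44 ± 0.34, the xyloglucan enzyme XTH6 by -2.21 ± 0.31, IAA17 by -1.68 ± 0.26 and ZEP by -1.49 ± 0.22. The vacuolar sorting gene tVPS41 (-1.28 ± 0.15), the blue-light receptor CRY1A (-1.22 ± 0.17) and the subtilisin-like protease SBT1 (-1.12 ± 0.15) were lower as well. With the mean of all probe sets of a gene IAA17 stood at -0.81 and CRY1A at -0.63, and neither was called (adjusted p = 0.0705 and 0.0986). Centred array medians ended the calls of UCP, gdh1, IAA17, ZEP, CRY1A and SBT1 (adjusted p from 0.0521 to 0.0526), and 16 added to each intensity that of LePK4 (0.0539). Quantile normalization ended those of UCP, gdh1 and IAA17 (adjusted p from 0.0524 to 0.0569), array weights those of UCP and SNF4 (0.054 and 0.078), and trend with robust moderation that of LePK4 (0.0594). Population as a random block ended those of SBT1, SNF4 and gdh1 (adjusted p = 0.272, 0.0533 and 0.0665). With population 1421, 1597 or 1630 left out no gene named here passed. Only 2 probe sets differed without 2618, and 10 without 1592. In all 148 probe sets differed by limma, 42 higher and 106 lower in pimpinellifolium. Without the 3 low-weight libraries 222 differed, and gdh1, SNF4 and ZEP no longer passed (adjusted p = 0.077, 0.115 and 0.0591). Without 1592 drought replicate 3 only 6 differed, and of the genes named here TAPG4 alone still passed. The count was 18 without 1592 drought replicate 2, 228 without 1592 drought replicate 1, 59 without 2618 drought replicate 4, 253 and 90 without 1421 drought replicates 1 and 4, 86 without 1597 drought replicate 3 and 80 without 1630 drought replicate 1; with plants as replicates it was 4626.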

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

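Tests chosen only after the result was seen were those of an exchanged pair, of a plant of its own population, of a drought response in the control library, and of the ethylene list without the 3 low-weight libraries. The search for single far values covered 4 library measures and the 20 genes of the averaged response, each in every group of 4 samples. Of these 240 combinations 29 held 1 (12.1%). Chance gives about 5% for a single combination, but the combinations were not independent. The genes were chosen for their drought response, so a drought library lying with the controls is far in many at once. Most far values lay in the low-weight libraries labelled drought. The share therefore cannot be set against 5%. Each value is the gap to the nearest other sample of the group as a share of the group's range.

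In 1597 drought replicate 3 the far values were those of the median intensity (0.923), the drought score (0.918), CHI17 (0.833), ER-SHSP (0.845), TAS14 (0.918), CHI3 (0.946), CEVI-1 (0.911), opr2 (0.966), ARPI (0.852), XET2 (0.837), BR1 (0.955), TPX2 (0.834), PT2 (0.904) and ST3 (0.940). In 1592 drought replicate 4 they were those of SNF4 (0.836), CHI17 (0.869), ER-SHSP (0.873), TAS14 (0.935), TSW12 (0.841) and PSY2 (0.843).

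These libraries labelled drought lay with the controls, and 4 explanations were weighed over 100 population marker probe sets chosen without the low-weight libraries, which assigned 43 of 43 other libraries to their labelled population. An exchange of a control and a drought library within a population needed a control with a score above 0, and 0 of 6 had one. For 1592 drought replicate 4 the distance to its own population (0.989) exceeded that to the nearest other, population 1421 of lycopersicum, by 0.755. The largest own distance among the 43 was 0.435. The low-weight library 1597 control replicate 2 also lay beyond it, at 0.774, but nearest to its own population. A large own distance alone therefore did not exclude a plant of the labelled population. For 1592 drought replicate 4 the nearness to 1421 (0.233) argued against such a plant. Over all probe sets its nearest libraries were the 4 controls of 1421 (r from 0.976 to 0.985), against a median of 0.9145 with its own group. A library from population 1421 under this label is a candidate explanation, found and tested on the same data. For 1597 drought replicate 3 the own distance minus the nearest other was -0.263, which argued against another population. With an own distance of 0.227, a plant of 1597 that was not short of water or did not respond, and a control plant under a drought label, cannot be told apart. Across probe sets this library correlated at 0.9909 with 1597 control replicate 1, above the highest value within any group (0.9884). Its median correlation with its own group was 0.9245.

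The library 1597 control replicate 2 stood apart from its group with the lowest array weight, 0.109, and wide differences between 3' and 5' control probe sets. They were 5.59 for actin, 7.58 for the elongation factor, 3.08 for GAPDH and 3.08 for ubiquitin, each the highest of the 46 arrays. The medians over the arrays were 1.34, 1.92, 0.876 and 0.146. Its deviation from the other controls of its population correlated across probe sets at 0.489 with the slope on the actin difference in the other libraries. Over the other 43 libraries the size of the same correlation had a median of 0.134 and a maximum of 0.522. This correlation therefore did not decide on RNA of lower integrity. The 3' to 5' differences themselves went with lower integrity, but other causes of them were not tested. The deviation correlated at 0.177 with the drought response of the other populations, between the bounds set for and against a drought response in the plant. No biological explanation beyond that was tested.

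The ethylene list responded differently in the species by camera at its preset correlation (adjusted p = 9.38e-09), a call that was lost with an estimated correlation (adjusted p = 0.109); its mean change was -1.21, -0.968 and -0.968 in the lycopersicum populations and -0.0028, -0.0597 and 0.142 in those of pimpinellifolium. The 3 low-weight libraries were excluded as its cause, since 21 and 2 members differed without them, against 22 and 1 with them (adjusted p = 1.61e-07 at the preset correlation). So was 1 population alone, since every mean of lycopersicum lay below every mean of pimpinellifolium (highest adjusted p with 1 population left out 2.01e-06, at the preset correlation). Within groups the members varied together, with a median pairwise correlation of 0.193 against 0.0233 for random lists, 100% of which lay lower. Lists not called in the interaction had higher estimated correlations than the ethylene list (0.188), such as ribosomal proteins (0.282) and reactive oxygen scavenging (0.21). The test therefore cannot point to handling at harvest. A shared response to handling that differed between groups was not excluded and stays open. A difference between the species in the response to drought, which the design names, stays open as well.

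Other far values lay in 2618 control replicate 1 for SNF4 (0.851), TSW12 (0.918) and PSY2 (0.876). Single far values were those of actin in 2618 drought replicate 4 (0.854), ER-SHSP in 1421 control replicate 4 (0.916), LIN8 in 1630 drought replicate 3 (0.977), PT2 in 1421 drought replicate 1 (0.932) and 2789 drought replicate 4 (0.880), and ST3 in 2789 drought replicate 1 (0.834).

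Differences between groups in the drought response were tested directly. Between the species 2598 probe sets differed, with limma adjusted p of 1.31e-07 for PTI5, AAP2 and DES, 7.61e-07 for ACS1A, 8.18e-07 for NCED1, 1.50e-06 for LEA14, 2.32e-06 for HT2 and ETR4, 2.59e-06 for ACS3 and 2.96e-06 for MPK3. Lists that differed by camera, and lost the call with an estimated correlation, were ethylene (9.38e-09), stress transcription factors (0.00246), pathogenesis-related genes (0.00447), the cell wall (0.0173), green shoot tissue (0.0295), jasmonate (0.035) and the added kinase list (0.0357).

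Among lycopersicum populations 391 probe sets differed, with adjusted p of 0.000199 for RNALE, 0.000288 for ETR5, 0.00131 for ETR4, 0.00185 for CAB4, 0.00291 for CIP1, 0.00301 for AGP-S2, 0.00322 for CPA, 0.00533 for WRKY2, 0.00628 for LEA14 and 0.00643 for abz1. Among pimpinellifolium populations 727 differed, with adjusted p of 6.17e-05 for FESOD, 0.0101 for PRK1, ZEP and THOM1, 0.0102 for RNALE, 0.0118 for PRK2 and 0.0123 for ACS8, DDTFR18, ER21 and MTSHP. That count was 25 without 1597 control replicate 2.

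Other splits of the samples were counted for every comparison. The averaged response (5594), that of lycopersicum (5185) and that of pimpinellifolium (4149) were each matched by 1 of 100 splits, the real one, and the highest other counts were 234, 227 and 659. The population differences in lycopersicum (391) and pimpinellifolium (727) were likewise matched by 1 of 100, with 131 and 92 as the highest others. Those splits also mixed plants of different populations within a group. Lasting differences between populations thereby entered the spread, which lowers the counts whatever the drought response. Such splits cannot exclude chance for differences in the drought response among populations. Chance was excluded for the averaged response and that of each species. It was also excluded for 2618 (3232, highest other 263), 1421 (3030, 1044), 2789 (2934, 913) and 1630 (2104, 1), each matched by 1 of 35 splits. Chance was not excluded by this count for 1597 (2375) or 1592 (2404), where 2 of 35 splits gave as many, the labelled one included. The highest others gave 3323 and 2959. Those other splits set 1597 drought replicate 3 and 1592 drought replicate 4, respectively, among the controls, which points to a structure of these samples. For the interaction (2598; highest other 1765) and the species differences in control (111; 0) and drought plants (148; 0), 10 splits are too few for a share under 0.05.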

How the results depend on the processing

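Settings that left out the 3 low-weight libraries, together or by treatment, were chosen after the data were seen; all others were planned. Of the comparisons of counts and list results with another setting, 972 stayed within 1.5 times the value reported (for r, within 0.0916) and 129 did not. For the 92 gene results, 1296 comparisons kept direction and call and 160 lost the call. With a library or replicate number left out, 4430 kept them and 170 lost the call, and 0 changed direction. Results of the F tests have no direction and were judged by the call alone. Most other genes were chosen for one direction in all their populations, so changes of direction were unlikely from the start. The cause of moved counts and lost calls was not tested except where stated.

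Leaving out the dimmest 25% of probe sets gave 292 for the species difference under drought and 1 called list in the averaged response. Array weights gave 4517 for the interaction, 249 and 349 for the species differences in control and drought plants, 3721 and 1616 for the population differences in lycopersicum and pimpinellifolium, 5288 for 1421 and 4454 for 1630. Trend with robust moderation gave 184 and 256 for the species differences, and 16 added to each value 298 under drought.

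A fold limit of 2 gave fewer by construction: 948 averaged, 1452 in lycopersicum, 993 in pimpinellifolium, 939 for the interaction, and 1524, 1534, 1173, 1236, 1129 and 1079 in 2618, 1421, 2789, 1597, 1630 and 1592. With 6 population-level responses, which leave fewer values, the averaged response gave 1987 and the interaction 0 (limma; 1697 at an unadjusted p under 0.05); without the 3 libraries they gave 2589 and 0 (1929). Individuals as replicates gave 2945 and 4626 for the species differences, and a random population block 818 and 1682. Own samples only gave 0 for 1597 (limma; 1754 unadjusted) and 374 for 1592.

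For lists, the estimated correlation left 0 calls in the averaged response and 0 in the interaction (camera), fry gave 12 and 11, and the mean of a gene's probe sets 1 in the averaged response. Lists called in the averaged response were 5 without population 2789 and 1 without population 1597, and in the interaction 3 without 1421. Species differences in control plants were 16, 5, 37, 337, 28 and 39 without 2618, 1421, 2789, 1597, 1630 and 1592. Under drought they were 2 and 10 without 2618 and 1592, and 0 (limma) without 1421, 1597 and 1630, with 2370, 2097 and 1870 at an unadjusted p under 0.05.

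Without the 3 libraries the populations of lycopersicum differed in 1353. None of the 3 was labelled lycopersicum, so its counts changed here only through the spread shared by all groups. Without those labelled drought the counts were 928 in lycopersicum, 1519 in pimpinellifolium and 3593 for 1597; without that labelled control they were 622, 25 and 640, with 1 list called.

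With each library or replicate number left out, counts ranged from 4667 to 5804 averaged, 4325 to 5419 in lycopersicum, 2762 to 4485 in pimpinellifolium, 1096 to 2890 for the interaction, 43 to 139 and 0 to 271 for the species differences in control and drought plants (limma; the 0, without replicate 3 everywhere, had 2058 unadjusted), 13 to 640 and 2 to 1797 for the population differences in lycopersicum and pimpinellifolium. They ranged from 2216 to 3507 in 2618, 1217 to 3328 in 1421, 1815 to 3216 in 2789, 1 to 3401 in 1597, 783 to 2341 in 1630 and 840 to 3067 in 1592. Called lists ranged from 1 to 4 averaged and 4 to 6 in the interaction, and r between the species from 0.361 to 0.592. A replicate number left out removes up to 12 libraries.

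Replicate numbers did not pair the samples: 22 pairs of one number correlated from -0.160 to 0.193 (median -0.00665), and in 5 of them a control sample correlated best with its own number. With the replicate block the averaged response gave 5646, the interaction 2625 and r 0.540. Dim values limit folds: with 16 added, the fold of SNF4 was 7.70 instead of 18.6.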

Other observations

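The 8 lists added after the table was seen were tested in the same way, and no other tests in this part were chosen after a result. Genes of isoprenoid and carotenoid synthesis gave 10 rises and 3 falls among 19 in the averaged response (camera, adjusted p = 0.137). Next to PSY2, ZEP rose by 1.65 ± 0.10, the plastid pathway gene DXS by 0.70 ± 0.09, and the farnesyl diphosphate synthase FPPS1 fell by 0.78 ± 0.10, each in 6 of 6 populations. The water deficit list gave 11 rises and 8 falls among 24 (camera, adjusted p = 0.137), with the proline transporter ProT2 at 1.73 ± 0.15 in 6 of 6 populations. In pimpinellifolium this list gave 13 rises and 3 falls (camera, adjusted p = 0.0178; adjusted p = 0.112 with an estimated correlation).

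Ascorbate and glutathione genes gave 3 rises and 5 falls among 12 (camera, adjusted p = 0.278), with GSH1 of glutathione synthesis at -0.80 ± 0.09, GMP at -0.81 ± 0.09 and the dehydroascorbate reductase DHAR2 at 0.45 ± 0.05. Amino acid, GABA and polyamine genes gave 2 rises and 6 falls among 14 (camera, adjusted p = 0.137), with the arginase ARG1 at 0.80 ± 0.09, the glutamate dehydrogenase gdh1 at -0.92 ± 0.12 and the glutamate decarboxylase gad2 at -0.91 ± 0.17. In lycopersicum 8 of these fell and 1 rose (camera, adjusted p = 0.0276; adjusted p = 0.476 with an estimated correlation).

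MAP and calcium-dependent kinases gave 1 rise and 6 falls among 10 in the averaged response (7 falls adjusted over the list alone; camera, adjusted p = 0.12), with CDPK1 at -0.65 ± 0.09 and MKK4 at -0.78 ± 0.12 in 6 of 6 populations. In lycopersicum 8 fell and 1 rose (camera, adjusted p = 0.0136; adjusted p = 0.476 with an estimated correlation). In the interaction 6 were more positive in pimpinellifolium and 1 in lycopersicum (7 and 1 adjusted over the list alone; camera, adjusted p = 0.0357; adjusted p = 0.576 with an estimated correlation), and without the 3 low-weight libraries the call ended at 0.0864.

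The 14-3-3 proteins gave 1 rise and 4 falls among 7 (camera, adjusted p = 0.202), with TFT6 at -1.26 ± 0.12; their median in lycopersicum, -0.14, turned to 0.04 with quantile normalization. Subtilisin-like proteases gave 0 rises and 3 falls among 6, sbt3 (-1.38 ± 0.14), SBT1 (-1.86 ± 0.28) and P69B (-1.70 ± 0.44), with a camera adjusted p of 0.128; in the interaction their median was -0.06 and the camera direction upward. Flower and fruit identity genes gave 1 rise, TDR8 (1.41 ± 0.19), and 0 falls among 10 (camera, adjusted p = 0.605), a list for tissue outside the root. No added list was called by camera between the species in control plants, where the smallest adjusted p was 0.275. The medians of the isoprenoid list in the interaction (0.02) and control plants (-0.00493), and of the kinase, amino acid and 14-3-3 lists in control plants (-0.08, -0.02 and -0.06), changed sign with scaling. In lycopersicum the ascorbate median was 0.01 and its mean -0.11.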
